A study of Mus musculus with 10 samples.

How the data were processed

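Quadriceps muscle RNA of 10 male mice, 5 Mut+/- and 5 Mut+/+, was measured with 1 Affymetrix 3' expression array per mouse. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was made by the 3' IVT Express procedure. The titles call the samples biological replicates. The groups and replicate numbers were taken from the genotype label and the title of each sample.

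The deposited values are probe set intensities on a linear scale. The authors' software was MAS5, per the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited table itself showed that every array had been scaled to the same mean, since the 2% trimmed mean of the signals was 1500.01 on all 10 arrays. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed. Single-channel arrays hold no read depth, and the number of arrays limits the precision. All 10 columns of the table matched a sample, and no pair of arrays held the same values.

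The table held 45101 probe sets, of which 64 were controls. The platform annotation gave exactly 1 gene symbol for 34945 of the others, several for 932 and none for 9160. Symbols were updated through the gene ID against a RefSeq gene table of assembly GRCm38.p6, in which 34754 of the probe sets with 1 symbol were found. That table also served to tell which genes lie near Mut. Probe sets with several symbols or none were tested apart, and of 3017 past the signal filter 0 passed an adjusted p of 0.05 (smallest 0.115).

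The signals were converted to log2 with no further normalization. Probe sets whose mean log2 signal was at or above the median (a signal of 254.5) were kept, 22519 in all, and for each gene the probe set with the highest mean was used, which left 11241 genes. Mut+/- was compared with Mut+/+ with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are Mut+/- minus Mut+/+. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists with at least 5 measured genes. An estimated correlation and fry were the alternatives. Single values were compared by a two-sided exact permutation test over all 252 assignments of the arrays. Files were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.

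The tests, the gene lists, the filter and the rule for named genes were set before the data were examined. The 31 lists were written from textbook knowledge of muscle, fasting, the Mut pathway and the other cell types that a dissected muscle could hold. The rule named Mut, and, if at least 5 genes passed, the 10 largest changes in each direction, otherwise the 10 genes with the smallest unadjusted p in each direction. It also named, from each list past camera and from the propionate, branched-chain amino acid, fatty acid oxidation, fibre type, fat-cell and clock lists, up to 4 members past the threshold or, where none passed, the 2 with the smallest p, and Nnt. Since fewer than 5 genes passed, the genes were named by unadjusted p.

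The fit was tested on simulated arrays of the 11241 genes with 200 genes changed in each of 10 rounds. It recovered 49.1% of genes with an absolute log2 difference of 0.5, 86.9% at 1 and 97.9% at 2, and 4.01% of its calls were false. The simulated noise was independent between genes and held no array apart from the others, so these rates need not hold for the real arrays. The alternatives were quantile normalization, median centring, an offset of 16, no filter or a stricter one at the 0.75 quantile of mean signal, all probe sets of a gene averaged or tested singly, moderation without the trend or with robust estimation, array weights, a replicate block, a fat-cell marker covariate, a 3' over 5' covariate, other thresholds and the omission of each array.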

Results

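Skeletal muscle gene expression was compared between male mice that carried 1 functional copy of the gene for methylmalonyl-CoA mutase (Mut+/-) and males with both copies (Mut+/+). Mut, now also named Mmut, encodes the mitochondrial enzyme that turns methylmalonyl-CoA into succinyl-CoA, the last step by which propionate, odd-chain fatty acids and several amino acids enter the TCA cycle. All mice had a C57BL6 background, received a diet with 45% of its energy from fat for 4 months from 5 weeks of age, and were fasted overnight. Quadriceps RNA was measured on 10 Affymetrix arrays, 5 per genotype. The array medians ran from 264 to 317 signal units, and pairs of arrays correlated at 0.904 to 0.922 over the probe sets.

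The Mut transcript was lower in Mut+/- than in Mut+/+ muscle on every array, as shown by both of its bright probe sets. For the probe set with the highest mean signal, the mean log2 signal was 12.55 ± 0.11 in Mut+/- and 13.08 ± 0.10 in Mut+/+ (SD, n = 5 each), or 69.4% of the Mut+/+ signal. For the second bright probe set it was 12.41 ± 0.04 against 13.22 ± 0.07, or 57.1%. The highest Mut+/- array lay below the lowest Mut+/+ array for each, with an exact permutation p of 0.00794, the smallest that 5 against 5 arrays allow. The limma fit took 1 probe set per gene, the brightest over all arrays. For Mut the log2 difference in this fit was -0.53 ± 0.08 (SE), with an adjusted p of 0.0595, just short of the threshold. The 2 bright probe sets were close to a tie, with mean signals of 7221 and 7199 over all arrays. In Mut+/+ the second was brighter (9530 against 8668), and in Mut+/- it was dimmer (5438 against 6016). The fit thus used the probe set with the smaller difference. With every probe set tested on its own, the adjusted p was 0.0473 for the brightest and 7.11e-05 for the second, whose log2 difference was -0.81. The remaining probe set of the gene was dim (signals of 39.0 and 37.5, exact permutation p = 0.952) and was below the signal filter. Which part of the gene the allele lacks relative to these probe sets is not given in the sources used here.

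**Figure D1:**
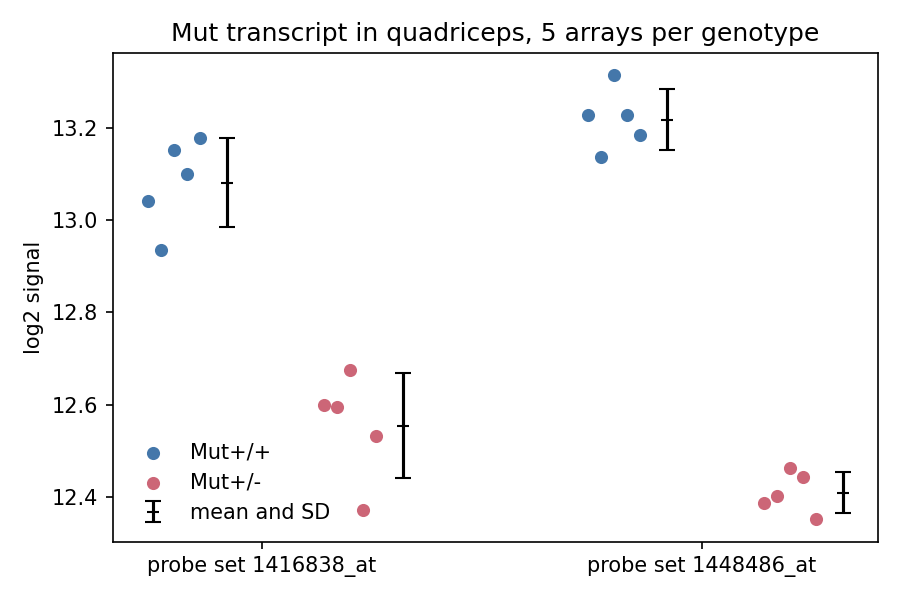
Log2 signal (vertical axis) of the 2 bright Mut probe sets on each array, with Mut+/+ in blue, Mut+/- in red, and the mean and SD of 5 arrays in black. The left pair of columns is the probe set with the highest mean over all arrays and the right pair the second. In the second the Mut+/- arrays lay between 12.35 and 12.46 and the Mut+/+ arrays between 13.14 and 13.31.

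Across the transcriptome, no gene passed the adjusted threshold, and the genes named here are those with the smallest unadjusted p in each direction. On the lower side, Actn2, the alpha-actinin of the Z-disc, had a log2 difference of -0.55 ± 0.10 (SE), Hk2, the muscle hexokinase that phosphorylates glucose after uptake, -0.46 ± 0.09, and Mfn2, a mitochondrial fusion GTPase, -0.31 ± 0.07. Nrap, a protein of myofibril assembly, stood at -0.29, the small heat shock protein Hspb6 at -0.32, and Egln3, an oxygen-sensing prolyl hydroxylase, at -0.47. On the higher side, the log2 difference was 1.49 ± 0.28 for Cd1d1, which presents lipid antigens to T cells, 0.62 ± 0.11 for Cdh5, the cadherin of endothelial junctions, and 0.70 ± 0.14 for Hpgd, which inactivates prostaglandins. It was 1.12 for the interferon-inducible helicase Ddx60, 0.77 for the oxysterol hydroxylase Cyp39a1, 0.63 for tissue factor F3 and 0.44 for the matrix proteoglycan Ogn.

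The remaining genes among the 10 with the smallest unadjusted p in each direction were Glb1l2 (log2 difference 1.21), Hmgn3 (0.62) and Pdcl (0.42) on the higher side and Ing5 (-0.53), Gpc1 (-0.32) and Maco1 (-0.30) on the lower side. Apart from Mut, these genes had adjusted p-values of 0.189 to 0.238, and none of the 20 overlapped between genotypes. For Cdh5 and Maco1, another probe set past the signal filter pointed the opposite way. Cd1d1 and Hpgd were highest in Mut+/- replicate 1, at 13.03 and 12.46, with the next Mut+/- array at 11.62 and 11.87. With the fat-cell marker score as a covariate the log2 difference was 0.58 for Cd1d1, 0.31 for Hpgd, 0.55 for Glb1l2, 0.27 for Hmgn3, -0.20 for Mfn2, -0.18 for Hspb6 and -0.21 for Gpc1.

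In the limma fit, 0 of 11241 genes passed an adjusted p of 0.05, and 1316 had an unadjusted p under 0.05, against 562 expected by chance, 699 of them (53.1%) higher and 617 lower in Mut+/-. With the fat-cell marker score as a covariate that number was 579, close to the 562 expected. This covariate separates the genotypes itself and raised the median standard error from 0.12 to 0.16, so lost precision may account for the lower count. The balance of directions depended on the scaling, with 48.5% higher after quantile normalization and 44.4% after median centring, and of the 139 that also differed by at least 1.5-fold 114 were higher and 25 lower. Groups did not overlap for 279 genes, or 2.48% of those tested, against 0.794% by chance. The count became 1 gene under several alternatives, Mut in each except without an intensity trend, where it was Ddx60 (adjusted p = 0.0133). The mean signal of Ddx60, 266, lay just above the filter cut, and its Mut+/+ signal lay below it. With every probe set tested on its own, 3 passed: both bright Mut probe sets and that of Scn7a, a sodium channel gene, with a log2 difference of 0.997 (adjusted p = 0.0473), which was named after its values were seen.

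**Figure D2:**
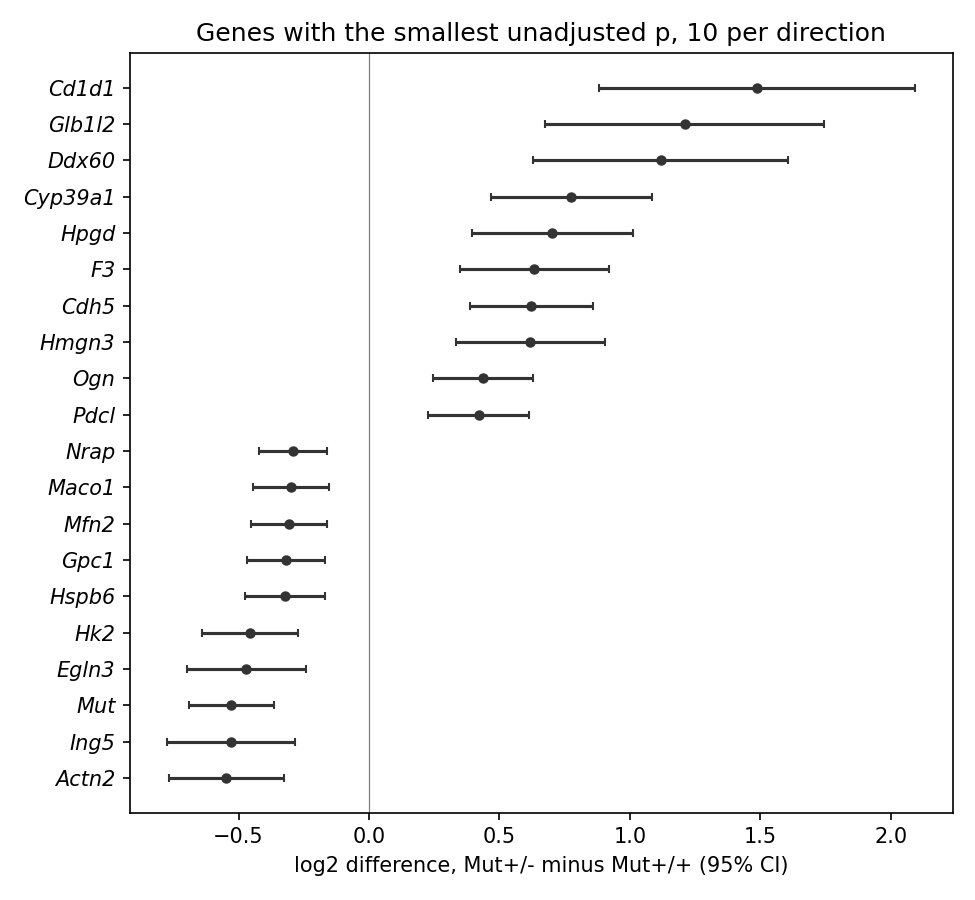
Log2 difference between Mut+/- and Mut+/+ (horizontal axis) for the 10 genes with the smallest unadjusted p in each direction; points are the limma estimates and bars their 95% confidence intervals. Cd1d1 had the highest value, 1.49, and Actn2 the lowest, -0.55, and no gene passed an adjusted p of 0.05.

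Genes of glucose use were lower in Mut+/- muscle by camera, a call lost with an estimated correlation (adjusted p = 0.569 with an estimated correlation). Of the 21 measured genes of glucose uptake, glycogen and glycolysis, 19 were lower, with a mean log2 difference of -0.13. Besides Hk2, the phosphorylase kinase subunit Phka1 stood at -0.23 ± 0.07 (SE). TCA cycle genes were lower in 15 of 19 members (mean -0.073), among them Cs, citrate synthase, at -0.23 ± 0.06 and Sdha, the catalytic subunit of succinate dehydrogenase, at -0.22 ± 0.07, although another Sdha probe set pointed the opposite way. The 18 circadian clock genes had a mean of -0.16, with 15 lower, including the repressor Bhlhe40 (-0.42) and the deubiquitinase Usp2 (-0.34).

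These 3 lists passed camera, with adjusted p-values of 1.99e-04, 0.00699 and 0.00699 in that order, and each had 2 members past 0.05 adjusted over the list alone and 0 over all genes. None held with an estimated correlation, with adjusted p = 0.569 with an estimated correlation for the glucose list, 0.738 for the TCA cycle and 0.569 for the clock. The TCA cycle list no longer passed with the mean of a gene's probe sets (-0.049, adjusted p = 0.0640) or without Mut+/+ replicate 3 (-0.066, adjusted p = 0.0505), nor did the clock list with a stricter signal filter (-0.10, adjusted p = 0.102) or with the fat-cell marker score as a covariate (-0.098, adjusted p = 0.364). The TCA cycle mean was -0.049 without Mut+/- replicate 1 (adjusted p = 0.0437). The clock score of Mut+/- replicate 1 was -0.27, with the other Mut+/- arrays between -0.051 and -0.017.

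Fast fibre, heat shock and mitochondrial chaperone genes were also lower by camera, calls lost with an estimated correlation (adjusted p = 0.738 with an estimated correlation for each). All 16 measured fast fibre markers were below Mut+/+ (mean log2 difference -0.11), with Myh2, the IIa myosin heavy chain, at -0.32 ± 0.10 (SE) and the calcium buffer Pvalb at -0.16 ± 0.08. Of 13 heat shock genes, 12 were lower (mean -0.20), among them Hsph1 (-0.40) and Cryab (-0.18). Of 14 mitochondrial chaperones and proteases, 10 were lower (mean -0.081), among them Hspa9 (-0.17) and Dnaja3 (-0.20).

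Camera gave these lists adjusted p-values of 0.00386, 0.00803 and 0.0435, with 0 members past 0.05 adjusted over the list alone and 0 over all genes, and each had an adjusted p = 0.738 with an estimated correlation. Mut+/+ replicates 3 and 5 had fast fibre scores of 0.22 and 0.19, and the other Mut+/+ arrays lay between -0.072 and -0.025. Without Mut+/+ replicate 3 the fast fibre mean was -0.069 (adjusted p = 0.0786), and after quantile normalization it was -0.058 (adjusted p = 0.122). With the fat-cell marker score as a covariate the fast fibre mean was -0.23 and the heat shock mean -0.35, with camera adjusted p-values of 1.14e-10 and 1.19e-04, but adjusted p = 0.503 with an estimated correlation for both. The heat shock list did not pass without Mut+/+ replicate 4 (-0.12, adjusted p = 0.0705) or without Mut+/- replicate 5 (-0.16, adjusted p = 0.0601), and the chaperone list lost its call under either scaling, with no signal filter or a stricter one, and without any of 5 single arrays.

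Markers of fat cells were higher in Mut+/- quadriceps by camera, a call lost with an estimated correlation (adjusted p = 0.641 with an estimated correlation). All 14 measured markers were above Mut+/+, with a mean log2 difference of 0.67, or 1.59-fold, among them the lipid droplet gene Cidec (1.27 ± 0.37, SE) and leptin, Lep (1.68 ± 0.51). The marker score of every Mut+/- array was above that of every Mut+/+ array, but by a narrow margin, since the lowest Mut+/- score was 0.025 and the highest Mut+/+ score 0.021. Mut+/- replicate 1 reached 1.17, the other Mut+/- arrays lay between 0.025 and 0.30, and Mut+/+ replicates 1 and 2 lay at -0.67 and -0.69.

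The fat-cell list passed camera with an adjusted p of 4.68e-06, and had 10 members past 0.05 adjusted over the list alone and 0 over all genes. It did not hold with an estimated correlation (adjusted p = 0.641 with an estimated correlation). Without Mut+/- replicate 1 the mean was 0.46 and the list still passed camera (adjusted p = 4.53e-05).

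Macrophage, fibroblast, endothelial and interferon response lists were also higher by camera, and none of these calls held with an estimated correlation. Of 21 macrophage markers 20 were higher in Mut+/- (mean log2 difference 0.26), with the galectin Lgals3 at 0.91 ± 0.31 (SE) and Aif1 at 0.49 ± 0.20. Of 24 fibroblast and extracellular matrix genes 22 were higher (mean 0.18), including Sparc (0.53 ± 0.16) and Dpt (0.36 ± 0.12). Endothelial markers were higher in 12 of 15 members (mean 0.17), led by Cdh5 and by Emcn at 0.32 ± 0.10. Of 20 interferon response genes 17 were higher (mean 0.14), with B2m, the light chain of MHC class I, at 0.36 ± 0.10 and H2-K1 at 0.34 ± 0.12, although another H2-K1 probe set pointed the opposite way.

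Camera gave adjusted p-values of 0.00485 for macrophage, 0.00593 for fibroblast and matrix, 0.00505 for endothelial and 0.0105 for interferon response genes. With an estimated correlation none held: adjusted p = 0.754 with an estimated correlation for macrophage, 0.738 for fibroblast and matrix, 0.572 for endothelial and 0.738 for interferon response genes. Adjusted over the list alone, 1 endothelial gene, 1 interferon response gene and 0 of the other lists passed, and over all genes 0. Each of these lists was highest in Mut+/- replicate 1, whose macrophage score was 0.85 against at most 0.045 on the other Mut+/- arrays. Without that array the macrophage (0.076, adjusted p = 0.357), matrix (0.096, adjusted p = 0.0817) and interferon response (0.066, adjusted p = 0.131) lists no longer passed, and the log2 difference was 0.56 for Lgals3, 0.22 for Dpt and 0.21 for H2-K1. Without Mut+/+ replicate 2 these lists did not pass either, at 0.17, 0.11 and 0.11, nor did the matrix list without Mut+/+ replicate 4, at 0.14. With the fat-cell marker score as a covariate, their means turned to -0.13, -0.031 and -0.063 and Sparc to -0.0040, and the endothelial mean was 0.050 (adjusted p = 0.454). The difference was then 0.091 for Lgals3, 0.32 for Aif1, 0.029 for Dpt, 0.094 for Emcn, 0.10 for B2m and 0.029 for H2-K1.

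**Figure D3:**
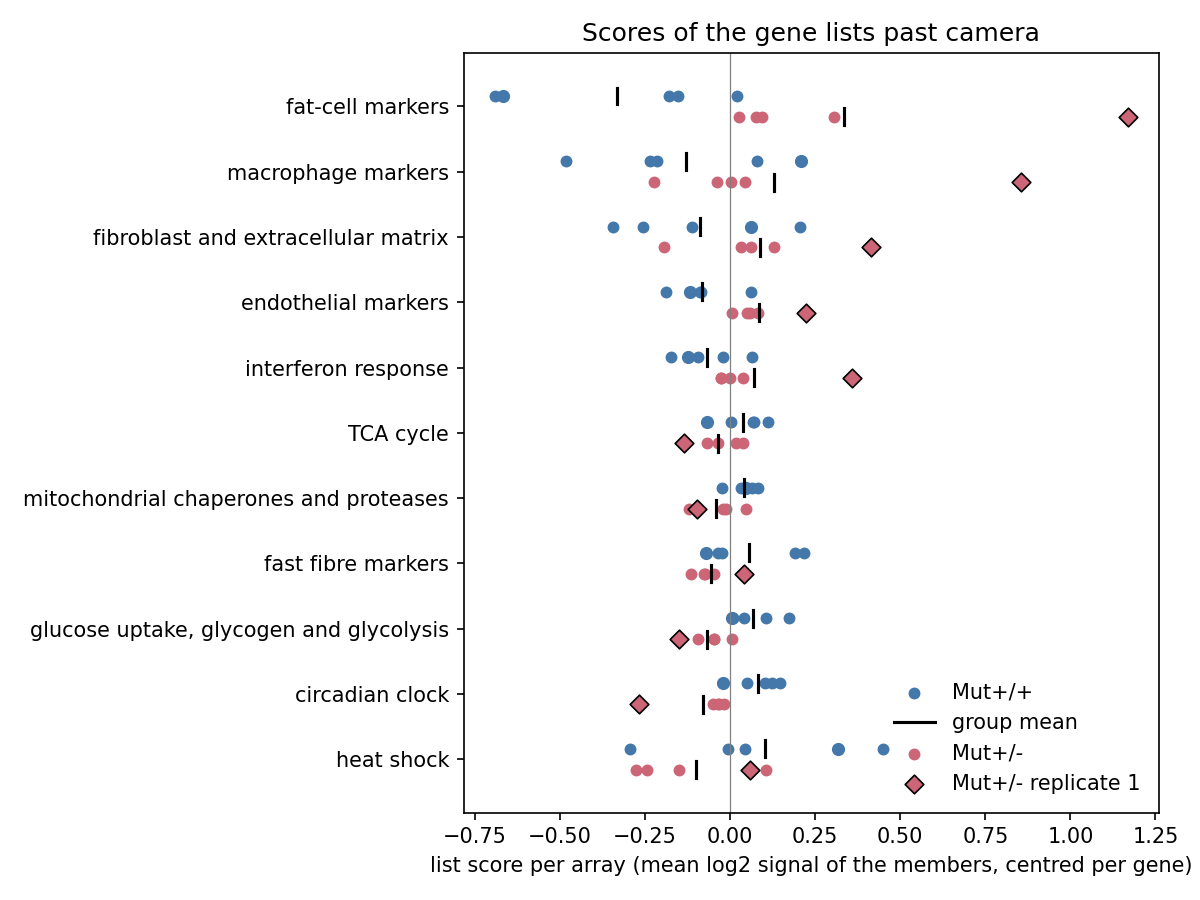
Score per array (horizontal axis, mean log2 signal of the members after centring each gene) of the 11 lists past camera, with Mut+/+ in blue, Mut+/- in red, group means as black bars and Mut+/- replicate 1 as an outlined diamond. For fat-cell markers replicate 1 stood at 1.17, while the other Mut+/- arrays lay between 0.025 and 0.30.

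The pathway of the Mut enzyme itself gave no call. Its 15 measured propionate and methylmalonyl-CoA genes had a mean log2 difference of -0.010 (camera adjusted p = 0.759), with Mtrr, a cobalamin-pathway reductase, at -0.25 ± 0.11 (SE) and Mcee, the epimerase one step before Mut, at 0.17 ± 0.09 (0.11 without Mut+/+ replicate 1). The 20 branched-chain amino acid genes averaged 0.0019 (adjusted p = 0.902), with the dehydrogenase kinase Bckdk at -0.14 (-0.090 without Mut+/- replicate 1) and Hibadh at -0.11. Fatty acid oxidation genes averaged -0.061 (adjusted p = 0.0535), with Eci1 at -0.20 and Acot2 at -0.19, and this list passed with the 3' over 5' ratio as a covariate (-0.089, adjusted p = 0.0142) and with some single arrays left out. Slow fibre markers averaged -0.030 (adjusted p = 0.902), a list for which camera's direction was up, with Pln at 0.43 and Tpm3 at 0.23 (0.15 without Mut+/- replicate 2), each with another probe set pointing the opposite way.

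The other lists also did not pass camera. Respiratory chain complex I averaged -0.023 (adjusted p = 0.293), complexes III to V -0.033 (0.106), insulin signalling -0.068 (0.112), PPAR targets 9.27e-04 (0.773), muscle atrophy and fasting genes -0.026 (0.325) and lipid synthesis genes 0.13 (0.304). The integrated stress response averaged 0.089 (0.682), antioxidant genes 0.024 (0.902), immediate early genes -0.13 with a median of 0.020 (0.770) and satellite cell genes -0.14 (0.293). Smooth muscle and pericyte markers averaged 0.14 (0.0621) and passed after quantile normalization (0.13, adjusted p = 0.0419), with a stricter signal filter (0.14, adjusted p = 0.0347) and without any of 3 single arrays. Insulin signalling passed without Mut+/+ replicate 5 (-0.096, adjusted p = 0.0457), while its mean was -0.017 without Mut+/+ replicate 1 (adjusted p = 0.616) and -0.014 with the fat-cell marker score as a covariate. Complex I passed without Mut+/+ replicate 1 (-0.059, adjusted p = 0.00874) or Mut+/- replicate 3 (-0.051, adjusted p = 0.0202), and complexes III to V without either of these (-0.066, adjusted p = 0.00245, and -0.057, adjusted p = 0.00799) or Mut+/+ replicate 2 (-0.059, adjusted p = 0.0162), while both means were above 0 without Mut+/+ replicate 5 (0.013 and 4.20e-04). Brown fat markers averaged 0.060 (0.926) and Schwann cell markers 0.035 (0.439). With single arrays left out, the mean ran from 0.059 (without Mut+/- replicate 1) to 0.17 for lipid synthesis, 0.049 (without Mut+/- replicate 1) to 0.12 for the integrated stress response and 0.0057 (without Mut+/+ replicate 2) to 0.048 for antioxidant genes. It ran from -0.22 to -0.050 (without Mut+/+ replicate 4) for immediate early genes, -0.21 to -0.050 (without Mut+/+ replicate 1) for satellite cell genes and 0.0049 (without Mut+/- replicate 2) to 0.11 for brown fat markers. For PPAR targets and branched-chain amino acid genes, camera's direction was down although the mean was above 0. Adjusted over the list alone, 2 PPAR targets, 1 insulin signalling gene and 1 smooth muscle gene passed. Lists of T and B cell (3 measured genes), red blood cell (4) and cell cycle genes (4) were too small to test and averaged 0.34, -0.20 and -0.11.

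A targeted allele can carry flanking sequence from another strain, so genes around Mut on chromosome 17 were compared with the rest. Cyp39a1 (log2 difference 0.77 ± 0.14, SE), Ppp1r11 (0.49 ± 0.12) and Cenpq (0.39 ± 0.11), which lies next to Mut, had the smallest unadjusted p-values within 5 Mb of it. None passed the adjusted threshold, and with 0 of 399 neighbours within 20 Mb and 0 of the other genes past it, the planned Fisher's exact test decided nothing. At an unadjusted p under 0.05, a threshold chosen after seeing the data, 60 neighbours (15.04%) and 11.6% of the other genes qualified, an odds ratio of 1.35 (95% CI 1.004 to 1.80, Fisher's exact p = 0.0390). Within 5 Mb it was 6 of 33 genes (18.2%), with an odds ratio of 1.68 (0.566 to 4.17, Fisher's exact p = 0.270).

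Nnt, a mitochondrial transhydrogenase gene that is partly deleted in the C57BL/6J substrain, was bright on all arrays and did not separate the genotypes. Of its bright probe sets, the dimmer had a log2 difference of -0.10 (exact permutation p = 0.151) and the brighter one of 0.12 (exact permutation p = 0.349). Where these probe sets lie relative to the deleted part is not given in the sources used here. Their signal therefore does not tell the substrain. The log2 ratio of 3' over 5' signal, a measure of RNA integrity, was 0.33 ± 0.09 in Mut+/- and 0.29 ± 0.06 in Mut+/+ for Actb (SD, n = 5 each, exact permutation p = 0.492). For Gapdh it was -0.26 ± 0.03 and -0.28 ± 0.01 (exact permutation p = 0.190).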

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

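The comparisons of each value with the other arrays of its group were set before the data were examined; the tests of the fat-cell markers, of the windows around Mut and of the TCA cycle list were chosen only after the result was seen. Of 166 groups of 5 arrays compared, 15 had an array far from the others, by a gap over 0.71 of the group's range, where chance gives about 1 in 20, or 8.3. Of these, 12 were values of Mut+/- replicate 1. For this array the ratio of gap to range was 0.755 for the fat-cell score, 0.752 for macrophage markers, 0.827 for the interferon response and 0.864 for the clock list, in which it was lowest. Among genes it was 0.881 for Cd1d1, 0.794 for Hpgd, 0.816 for Sparc, 0.829 for Emcn and 0.748 for H2-K1, in which replicate 1 was highest, and 0.852 for Hspb6, 0.720 for Cs and 0.789 for Bckdk, in which it was lowest. The other values apart were the highest of Mut+/+, Nrap in replicate 2 (0.768), Hspb6 in replicate 1 (0.832) and the 3' over 5' ratio of Actb in replicate 5 (0.829).

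Fat-cell markers were higher in Mut+/- muscle by 0.67 on the log2 scale. If the sample rich in fat-cell RNA were the whole cause, nearly all of the difference should be lost without it. The cut, set after the result was seen, was a fall below 50% of its size. Without Mut+/- replicate 1, 68.7% was left, and the list still passed camera, though its call with all arrays is lost with an estimated correlation (adjusted p = 0.641 with an estimated correlation). That array thus did not carry the whole difference, but part of it rested on that array. Within genotypes the markers varied together, with a median pairwise correlation of 0.677, as differing amounts of fat-cell RNA in the dissected pieces would give. This correlation includes Mut+/- replicate 1 and was not computed without it. Whether Mut+/- muscle holds more fat or the dissection took more of it is open, since no measure of tissue makeup was analysed here, and a genotype effect stays untested.

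Genes of glucose use and of the TCA cycle were lower in Mut+/- muscle. For dilution by fat-cell RNA, the fat-cell score was used as a covariate. It left 99.1% of the glucose list's difference and 94.8% of that of the TCA cycle, both still past camera but with adjusted p = 0.503 and 0.696 with an estimated correlation in that fit. The score separates the genotypes itself, and with it the fast fibre mean went from -0.11 to -0.23, the opposite of a correction for dilution. This fit therefore cannot decide on dilution, which stays open. With the covariate the genes with an unadjusted p under 0.05 went from 1316 to 579, against 562 expected by chance, while the median standard error rose from 0.12 to 0.16. For a shift of all abundant transcripts, the lists were set against 10000 random lists of like signal. The glucose mean, -0.13, lay at percentile 0 of these, whose median was -0.023, and the TCA cycle mean at percentile 5.94. The random lists were drawn gene by gene and lack the correlation between members, so such percentiles come out too extreme. Immediate early genes, which were not called, also lay low, at percentile 0.25. The glucose mean was thus lower than that of transcripts of like signal, but such a shift is not excluded for it and stays open for the TCA cycle. The genotype and any technical difference not measured here stay open, and without the covariate the lists had adjusted p = 0.569 and 0.738 with an estimated correlation.

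More genes near Mut than elsewhere had an unadjusted p under 0.05. The share within 20 Mb, 15.04%, was at percentile 97.1 of 3331 overlapping windows of as many neighbouring genes elsewhere, whose median was 11.5%. Within 5 Mb it was 18.2% against a median of 12.1%, at percentile 81.9 of windows of 33 genes. The threshold and the comparison with windows were chosen after the excess was seen, and the 20 Mb and 5 Mb windows differ in outcome, so whether the share exceeds that elsewhere stays open. Flanking sequence from another strain may contribute, which these arrays do not test.

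Chance was tested with 100 of the 126 splits of the 10 arrays into 5 and 5. For genes past an adjusted p of 0.05 the splits decide nothing, since the real split gave 0 and all 100 must reach that (highest other 1). For genes with an unadjusted p under 0.05, 3 of the 100 splits, the real one included, gave at least its 1316 (highest other 1512). This share is under 0.05, which speaks against chance for that count but does not exclude it. The splits did not use the fat-cell covariate, with which the count was 579 against 562 expected by chance, so the excess is not shown to be separate from the fat-cell markers. For gene lists past camera, 11 splits gave at least the real 11 (highest other 15, median 6), so chance cannot be excluded for the number of lists.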

How the results depend on the processing

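The second Mut probe set, the exact test of list scores, the unadjusted threshold and 5 Mb window near Mut, the fat-cell covariate for single lists, this covariate with an estimated correlation, the joint omission of 2 arrays and all settings of the sarcomere list were chosen after seeing the data. The count of genes past the threshold, 0, became 1 with the stricter signal filter, with the mean of a gene's probe sets, without an intensity trend, with robust moderation, with array weights and at an adjusted p under 0.1, 3 with every probe set on its own, 139 at an unadjusted p under 0.05 with 1.5-fold, and 0 to 1 with single arrays left out (1 without Mut+/+ replicate 2). The Mut difference passed with the stricter filter (-0.53, adjusted p = 0.0425), with the mean of probe sets (-0.67, 4.20e-04), robust moderation (-0.53, 0.0439), array weights (-0.56, 0.0242) and the second bright probe set (-0.81, 7.11e-05), and ran from -0.56 to -0.48 with single arrays left out. Fewer genes tested lower the adjusted p with the stricter filter; the other causes were not tested. The count of lists past camera, 11, was 6 of 27 with the fat-cell covariate (the fat-cell list cannot be tested there; 4 of the other 10 called lists and 2 lists not called before), 7 to 15 with single arrays left out (7 without Mut+/- replicate 1), 5 without Mut+/- replicate 1 and Mut+/+ replicate 5 together, the latter picked by its own fat-cell score, and 0 with an estimated correlation, fry or the exact test of list scores (smallest adjusted p 0.148). In the exact test fat-cell markers reached the smallest p possible, 0.00794, and still had an adjusted p of 0.148. That test could thus pass no list by itself, and its 0 is no evidence against the lists. In the joint omission the TCA cycle, chaperone, clock, interferon response, macrophage and matrix lists lost their calls. Near Mut, the count of 0 became 60 at an unadjusted p under 0.05. With the replicate block, 0 genes passed, 1418 had an unadjusted p under 0.05 and 10 lists passed, the chaperone list losing its call; the numbers do not pair the arrays, as 1 of 5 same-number pairs correlated over 0.1 and 2 of 10 arrays correlated best with their own number. Signs turned with the fat-cell covariate for Sparc (-0.0040) and for the lists of propionate (0.071), PPAR (-0.11), lipid synthesis (-0.083), integrated stress (-0.037), antioxidant (-0.054), interferon (-0.063), slow fibre (0.074), brown fat (-0.030), macrophage (-0.13), matrix (-0.031) and Schwann cell genes (-0.042); complex I (-0.11, adjusted p = 1.59e-05) and complexes III to V (-0.14, 1.10e-08) passed with it, but 0 lists did with it and an estimated correlation (0.696 for both). This covariate separates the genotypes itself and raised the median standard error from 0.12 to 0.16; with it the mean was -0.0081 for atrophy, 0.019 for smooth muscle and pericyte, -0.070 for satellite cell, -0.090 for immediate early and 0.040 for branched-chain amino acid genes. Lists that were not called also turned: branched-chain amino acid genes with median centring (-0.020), with the stricter filter (-0.0070), with the mean of probe sets (-0.0048) and with the 3' over 5' covariate (-0.011); PPAR targets with quantile normalization (-6.72e-04), median centring (-0.021), the mean of probe sets (-0.0077) and the joint omission (-0.026); complex I with no filter (0.0021) and the joint omission (0.013); immediate early genes with the stricter filter (0.045); slow fibre with the 3' over 5' covariate (0.034); propionate (0.030) and Schwann cell genes (-0.040) with the joint omission. With single arrays left out, the ranges that cross 0 were -0.019 to 0.022 for branched-chain amino acid, -0.067 to 0.0080 for atrophy, -0.045 to 0.025 for PPAR, -0.038 to 0.032 for propionate, -0.059 to 0.013 for complex I, -0.066 to 4.20e-04 for complexes III to V, -0.016 to 0.10 for Schwann cell and -0.33 to 0.18 for slow fibre genes. The mean of the sarcomere genes not seen in advance ran from -0.15 to -0.096 with single arrays left out. Of the other results for single genes and lists, 1074 and 521 kept direction and side of the threshold. A call was lost in 0 and 62, where no such gene had one to lose, and gained in 1 and 18. The cause of these changes was not tested. Dim probe sets, such as the third of Mut, limit what can be compared at low signal.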

Other observations

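The sarcomere list and its tests were chosen after gene values were seen. Several sarcomere and Z-disc genes were lower in Mut+/- muscle without passing the adjusted threshold, among them Actn2 (-0.55 on the log2 scale), Nrap (-0.29), Fhod1 (-0.40), Myom2 (-0.20), Mybpc1 (-0.20) and Des (-0.16). Of 38 measured genes of a sarcomere list, 32 were lower, with a mean of -0.16. The hypothesis that sarcomere genes are lower as a group was first tested on all of them with limma's camera, whose p was 2.56e-09. Because 6 members had been seen among the lower genes when the list was written, the test was then set again on the other 32, after that first result was known, of which 26 were lower, with a mean of -0.13. Their mean lay at percentile 0.17 of 10000 random lists of like signal, which lack the correlation between members. Camera gave p = 1.28e-05, but p was 0.0356 with an estimated correlation, and an exact permutation test of the list score gave 0.0714. These p-values are unadjusted, unlike those given for the fixed lists. Unadjusted, the glucose and clock lists had p = 0.0407 and 0.0381 with an estimated correlation, and an exact permutation p of 0.0159 each. For the 32 sarcomere genes the p with an estimated correlation was 0.187 after quantile normalization, 0.172 after median centring and 0.0690 with a stricter signal filter. It was under 0.05 in 4 of 10 omissions of a single array (0.0176 to 0.0603). In the same Mut+/- arrays fat-cell (0.67), macrophage (0.26) and matrix (0.18) markers were higher. With the fat-cell score as a covariate the mean of the 32 genes was -0.070 (camera p = 0.00666, and p = 0.169 with an estimated correlation). The same covariate moved the fast fibre mean from -0.11 to -0.23 and that of complexes III to V from -0.033 to -0.14. Dilution of muscle RNA would move such lists the other way, so this covariate cannot decide whether dilution accounts for part of the sarcomere difference. Whether sarcomere transcripts are lower as a group stays open.

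Immunoglobulin kappa signal was higher in Mut+/- muscle on 3 probe sets that list several kappa symbols, by 2.68-fold to 2.96-fold, with an adjusted p of 0.115 each in the limma fit of probe sets without a single symbol. They were singled out after their values were seen. Ubd, an interferon-inducible ubiquitin-like gene near Mut, had a log2 difference of 1.77 ± 0.58 (SE) and an unadjusted p of 0.00810.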
